A study of Mus musculus with 2 samples.

How the data were processed

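DNase-seq was deposited for 2 libraries of spleen from 10-day-old male mice, biological replicates 1 and 2 of 1 group. The deposited README gives, per library, 2 peak lists, a list of footprints, a list of false discovery rates of the cut rate, and the assembly mm10. The file ends lay within the chromosome lengths of the GRCm38 reference used here. Per the deposited README, each file derives from its own library's filtered alignment, and the libraries were not pooled. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here.

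The signal of each peak, as deposited by the authors, was a depth-scaled density: 100% of the values of replicate 1 and 99.999% of those of replicate 2 were whole multiples of a step of their library. The tolerance was 0.05 of a step, which was 0.00375 in replicate 1 and 0.00419 in replicate 2. The constant behind the step is not given in the sources used here, so signals compare within a library, and between libraries only as ratios. The FDR values, as deposited by the authors, were listed per stretch of bases and lay below 0.05. Every peak of the longer list held bases below 0.05, and every peak of the shorter list reached a value below 0.001. The longer list was used. The value column of the footprints, as deposited, was the constant 0.01 and was not used, so footprints were not ranked.

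Peaks were compared by overlap of at least 1 bp, and peaks of both libraries that overlapped were merged into sites, each with the strongest signal per library. Chance overlap came from 100 circular shifts of a list along each chromosome. Positions used GENCODE release M21: a promoter was the 500 bp either side of any TSS, then exon, intron and intergenic by peak midpoint. Exact binomial (Clopper-Pearson) intervals of 95% were given for shares. Densities were per Mb of called bases.

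Gene lists (18, with 270 genes of which 269 matched the annotation), 20 loci, 22 consensus sequences and all tests were chosen before the data were examined, except where stated. The lists were red cell, heme synthesis, B cell, T cell, NK, macrophage, neutrophil, dendritic, megakaryocyte, progenitor, stroma, endothelium, proliferation and housekeeping genes, and liver, neuron, muscle and pancreas genes as controls. A promoter counted when a peak lay within 500 bp of any TSS of the gene in both libraries. Each list was set against the remaining protein-coding genes by a 2-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists. Distal sites were sites in both libraries outside all promoters and within 50 kb of the most upstream TSS. Their mean per list was set against 10000 random lists of the same size matched on gene density, with a 2-sided permutation p adjusted over the lists. Loci were gene spans with 50 kb either side.

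Each footprint was extended by 5 bp either side and paired with an interval of equal width at a random position of the same peak outside footprints. A place was found for 229126 of the 307735 footprints in peaks of replicate 1 and for 190345 of 228976 in replicate 2. Consensus rates were compared by 2-sided Fisher's exact tests, adjusted over sequences and libraries, with 95% intervals of the ratio. A count of 0 was set to 3 for a bound. Chance sharing of footprints came from 100 random placements inside bases covered by peaks of both libraries.

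From each list the genes named were the 2 with the highest mean promoter signal and the gene with the most distal sites in both libraries. From each control list up to 3 genes with a promoter peak in either library were added. All loci and sequences were named, with the 5 strongest sites, the 5 strongest distal sites, the X and Y chromosomes and the autosomes with the highest and lowest density. Not every gene this rule picked is printed. Features named outside this rule are said to be so where they appear.

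The alternatives were the shorter deposited list, the stronger part of each list (at or above the median signal), autosomes only, merging within 150 bp, reciprocal overlap, other promoter windows (1000 bp, 100 bp), protein-coding or most upstream TSSs, matching on CpG content or none on gene density, other distal windows (25 kb, 100 kb), nearest gene, false discovery thresholds of 0.01 and 0.001, footprint width, extension (0 and 10 bp) and background, and leaving out each replicate. Tested on simulated data, the promoter test called a list in 3% of runs without an effect and recovered 85% of planted lists with 95% open promoters. The distal test gave 5% and recovered 70% of lists planted at 2 times the mean. Its simulated counts were drawn gene by gene, so sites shared by windows of neighbouring genes were not simulated. The test of signal ratios by list gave 5% and recovered 100% at a log2 shift of -0.4. Its simulated values were also drawn gene by gene, and matched on gene density where the test itself matched on signal. A consensus planted at a ratio of 5.38 was recovered at 5.20. Overlap counts differed by 0 from bedtools 2.31.1.

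Random draws used seed 20. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1, blastn 2.17.0 and matplotlib 3.10.9. Not used here were read-level data, the README beyond provenance, and sequences outside chromosomes 1 to 19, X and Y. Reads of the CAST/EiJ copy can map less well to a C57BL/6 reference, and alleles were not analysed here.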

Results

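Chromatin accessibility was measured by DNase-seq, in which DNase I cuts exposed DNA in nuclei and the cut ends are sequenced, in spleen of 10-day-old male B6CASTF1/J mice. This strain is the first-generation cross of a C57BL/6 and a CAST/EiJ parent. The series held 2 libraries in 1 group, biological replicates 1 and 2, taken as separate animals because the labels number them separately, under a shared donor identifier. With 1 group there was no contrast between conditions, and each value is given per library or for features found in both. Positions are on mm10. Read totals were not analysed here, so the absolute depth is unknown. The smallest step between peak signals gave a relative depth of 1.12 for replicate 1 over replicate 2, if both were scaled by total depth in the same way, which is not stated. Replicate 1 had 130476 peaks covering 24.5 Mb and replicate 2 had 95847 peaks covering 19.2 Mb, with a median width of 180 bp in both. The median peak signal was 0.578 in replicate 1 and 0.553 in replicate 2. Stretches below a false discovery rate of 0.05 numbered 207085 over 40.6 Mb in replicate 1 and 182843 over 31.0 Mb in replicate 2. Intervals are 95% and cover counting error only.

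Accessible sites with strong signal were found in both spleens, and most sites called in a single spleen were weak. Sites merged from both libraries numbered 146575, of which 73150 (49.9%) held a peak of both, 53516 a peak of replicate 1 alone and 19909 a peak of replicate 2 alone. Of the replicate 1 peaks, 58.1% overlapped a replicate 2 peak by at least 1 bp, and of the replicate 2 peaks 78.8% overlapped a replicate 1 peak. Shifting the peaks along their chromosomes 100 times gave means of 1.45% and 1.95%. With both lists held to their 95847 strongest peaks the shares were 74.6% and 74.5%, and with the strongest 20000 they were 88.6% and 88.4%. The share found rose with signal from 2.90% (2.62 to 3.21) to 99.1% (98.9 to 99.3) over signal deciles of replicate 1 peaks, and from 34.7% (33.7 to 35.7) to 99.7% (99.6 to 99.8) over those of replicate 2. Across sites in both, signals had a Spearman coefficient of 0.922, and the log2 ratio of replicate 1 to replicate 2 had a median of 0.84 and an SD of 0.58. Sites are not independent replicates.

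**Figure D1:**
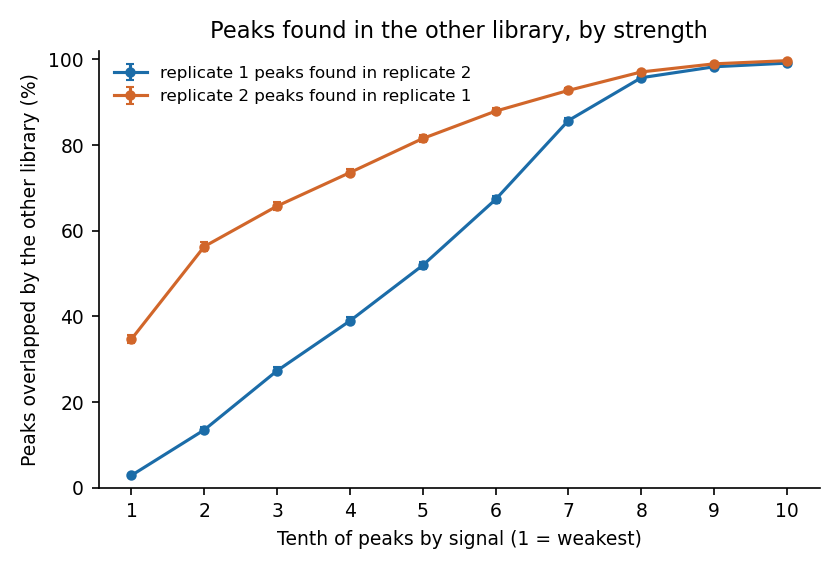
Share of each library's peaks overlapped by a peak of the other (vertical axis, %) by decile of peak signal (horizontal axis, 1 is the weakest), with exact 95% intervals. The share rose from 2.90% to 99.1% for replicate 1 peaks and from 34.7% to 99.7% for replicate 2 peaks.

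Promoters, the 500 bp either side of an annotated transcription start site (TSS), held most of the strongest accessible sites. Introns held the largest share of all peaks in each library. Promoters held 24.2% (23.9 to 24.4) of replicate 1 peaks, 27.2% (26.9 to 27.5) of replicate 2 peaks and 21946 of the 73150 sites in both. Promoter windows made up 3.26% of the called genome. Introns held 36.9% of replicate 1 peaks and 37.6% of replicate 2 peaks, intergenic DNA 30.9% and 28.9%, and exons 8.03% and 6.35%. Among sites in both, 83.8% (82.9 to 84.6) of the top decile by signal lay in promoters. Sites in replicate 1 alone lay in promoters in 15.2% of cases and sites in replicate 2 alone in 14.9%. The share in promoters depended on the window, with a mean of both libraries of 34.8% at 1000 bp and 13.5% at 100 bp.

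Peaks were densest on chromosome 11 and, among autosomes, sparsest on chromosome 3 by the mean of both libraries. The X chromosome, present in 1 copy in males, had fewer and weaker peaks per Mb than the autosomes, and the Y chromosome had almost none. Chromosome 11 had 84.9 peaks per Mb in replicate 1 and 62.3 in replicate 2, against 37.8 and 29.2 on chromosome 3. In replicate 2, chromosome 14 was slightly lower than chromosome 3. The X chromosome had 21.4 and 16.9 peaks per Mb, which was 0.396 and 0.438 of the median autosome. The median signal of its peaks was 0.538 and 0.552 of the autosomal median. The Y chromosome had 1.37 and 1.79 peaks per Mb. No test was made of these densities.

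Red cell loci were dense with accessible sites in both spleens, as were some B cell, neutrophil and T cell loci. The beta-globin locus, which encodes the beta chains of hemoglobin, held 17 sites in both libraries within 50 kb of its genes, and the alpha-globin locus held 30. Loci of the red cell transcription factors Gata1, Tal1 and Klf1 held 15, 20 and 22. Replicate 2, which had fewer peaks genome-wide, had more than replicate 1 at beta-globin (30 against 21) and at alpha-globin (51 against 43). The B cell loci Pax5, Ebf1 and Cd79a held 27, 23 and 20 sites in both. Elane and Prtn3, which encode granule proteases of neutrophils, together held 20, the T cell coreceptor Cd4 17, and Bcl11b, a T cell transcription factor, 4. The blood progenitor loci Runx1, Spi1, Gata2 and Kit held 20, 10, 8 and 2. At Gata2, replicate 1 had 23 peaks and replicate 2 had 9. Spic, needed for red pulp macrophages, held 5, Tlx1, needed to form the spleen, 7, and the platelet chemokine genes Pf4 and Ppbp 2. Of the control loci, liver Alb held 2 and heart Myh6 and Myh7 held 11. The 18 tissue loci had a median of 8.47 sites in both per 100 kb, against 2.76 over the genome. The heart control locus had 7.20, near that median, and the liver control 1.73, so a density above the genome's was not limited to tissue loci. Windows differ in length: per 100 kb, alpha-globin had 24.8, Klf1 21.3, Tal1 17.3, Gata1 12.6 and beta-globin 12.1. Cd79a had 19.1, Elane and Prtn3 17.6 and Cd4 13.8, each above Gata1 and beta-globin. Gata2 had 7.07, Tlx1 6.59, Runx1 6.16, Ebf1 4.69, Spic 4.54, Bcl11b 2.07, Pf4 and Ppbp 1.91 and Kit 1.1, all below the heart control. Kit was also below the liver control. Counts include sites at neighbouring genes in the window. No site in both lay inside Cd4, Elane, Spic, Pf4 or Ppbp, and no promoter of these genes had a peak in either library. Each locus was described without a test.

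In the beta-globin locus the strongest site by mean signal was intergenic, at chromosome 7, 103861001 to 103861200, with a signal of 9.38 in replicate 1 and 4.45 in replicate 2. The promoters of the adult genes Hbb-bs and Hbb-bt had signals of 5.12 and 4.10 in replicate 1 and of 5.07 and 4.46 in replicate 2. At alpha-globin, the Hba-a1 promoter had signals of 1.02 and 0.733, and no peak was listed at the Hba-a2 promoter. Hba-a1 and Hba-a2 are near-identical copies, so values there are uncertain. Copies of the promoter sites of either globin locus were not searched for.

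**Figure D2:**
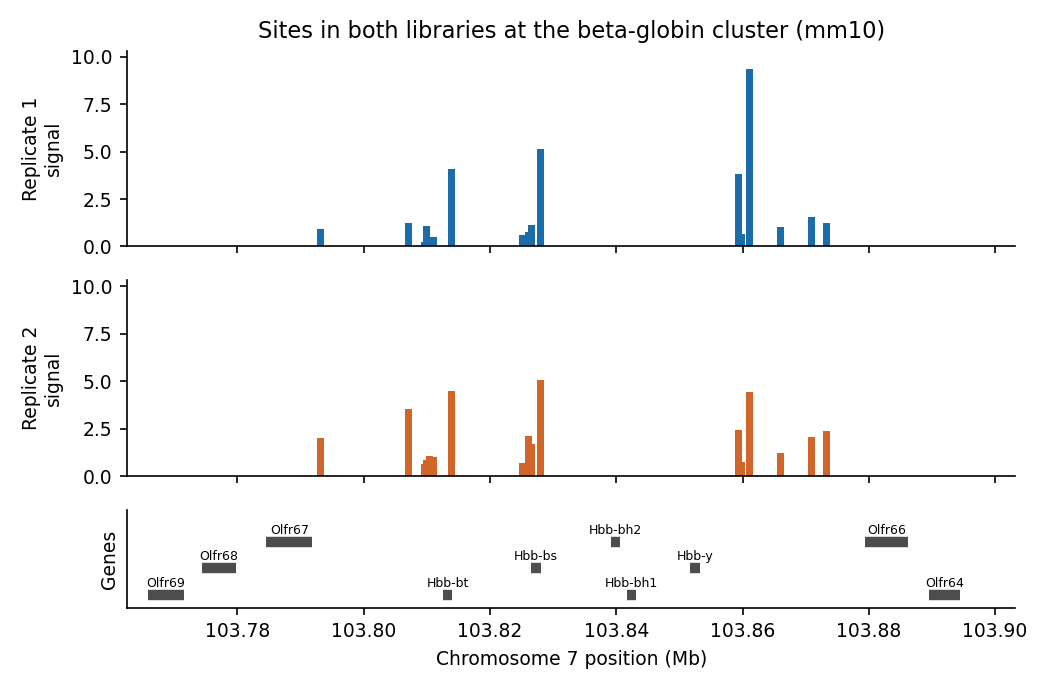
Map of the beta-globin locus on chromosome 7 (horizontal axis, position on mm10), with the peak signal of each library (vertical axes) and the genes. Among the sites drawn, found in both libraries, the strongest by mean signal had 9.38 in replicate 1 and 4.45 in replicate 2, where the Hbb-bs promoter was higher at 5.07.

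Over the genome, the site in both libraries with the highest mean signal was intergenic on the X chromosome, 143482981 to 143483120, 35540 bp from the TSS of Pak3, with signals of 39.1 and 132. The next were at 3002461 to 3002646 on chromosome 9 (53.1 and 72.5), at 3019081 to 3019207 on chromosome 9 (94.2 and 22.5), at the promoter of the dynein light chain gene Dynlt1b on chromosome 17 (77.3 and 29.2), and at the promoter of the cell cycle gene Fzr1 on chromosome 10 (77.6 and 22.7). Outside promoters the list continued with an exon of Lars2 on chromosome 9 (43.4 and 34.2), an exon of Cers5 on chromosome 15 (36.8 and 33.1), and a site on chromosome 8 (49.8 and 18.2), 586 bp from the TSS of Ell. The site near Pak3, both sites near the start of chromosome 9, the Dynlt1b site and the Lars2 site had at least 1 near-identical copy elsewhere in the genome, which makes their signal uncertain.

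Promoters of red cell, heme synthesis and B cell genes were accessible in both spleens more often than those of other protein-coding genes. So were promoters of blood progenitor, proliferation and housekeeping genes, while no liver promoter of the list had a peak in both. Among red cell genes the strongest promoters were those of Tfrc, the transferrin receptor that takes up iron, and Epor, the erythropoietin receptor. Among heme synthesis genes they were Slc25a38, a mitochondrial glycine carrier, and Urod, a heme pathway enzyme. Among B cell genes they were Cd22, an inhibitory receptor, and Ebf1, a lineage transcription factor. Of 21911 protein-coding genes, 13305 (60.7%) had a promoter peak in both libraries. The lists above other genes were red cell genes (24 of 25, 96%, adjusted p 0.000939), heme synthesis (10 of 10, adjusted p 0.0212), B cell (19 of 21, 90.5%, adjusted p 0.0172), progenitor (13 of 14, 92.9%, adjusted p 0.0259), proliferation (12 of 12, adjusted p 0.0172) and housekeeping genes (16 of 16, adjusted p 0.00264), by 2-sided Fisher's exact tests over 18 lists. The lists below were liver (0 of 12, adjusted p 0.000242), megakaryocyte (3 of 14, adjusted p 0.0172), and natural killer (NK), neuron and pancreas genes (3 of 12 and adjusted p 0.0259 each), by the same exact tests. T cell (13 of 20, 65%), macrophage (11 of 20, 55%), neutrophil (8 of 17, 47.1%), dendritic (7 of 11, 63.6%), stroma (6 of 17, 35.3%), endothelium (6 of 12, 50%) and muscle genes (4 of 12, 33.3%) were not called. Against random genes matched on promoter CpG content, which separates broadly active promoters from the rest, red cell (37.0% in matched genes) and B cell genes (33.8%) were still above, at a permutation adjusted p of 0.0018 each. CpG content was taken within 500 bp of the most upstream TSS and matched in terciles, while a peak counted at any TSS. The other 9 called lists were no longer called after that matching, though some differences stayed large, with 92.9% against 65.9% in matched genes for progenitor (permutation adjusted p 0.0583), 100% against 71.9% for heme synthesis (0.0873) and 0% against 31.9% for liver genes (0.0516). Of these, heme synthesis was also not called in replicate 1 alone (exact adjusted p 0.0548), megakaryocyte in replicate 2 alone (exact adjusted p 0.0863) and neuron in replicate 1 alone, where 66.7% of promoters had a peak (exact adjusted p 1). Some lists gained a call below other genes. Stroma did in 5 of 8 alternatives (exact adjusted p 0.0128 to 0.0424), with other promoter definitions, stronger peaks or the shorter lists, but not in replicate 1 alone (58.8%, exact adjusted p 0.571) or matched on CpG (permutation adjusted p 0.868). Muscle did in replicate 1 alone (exact adjusted p 0.0444), at 100 bp (0.00447) and with the most upstream TSS (0.0215). Neutrophil did with stronger peaks (exact adjusted p 0.0424) and the shorter lists (0.0229), and T cell with stronger peaks (25%, 0.0424). T cell promoters lay above other genes, without a call, in replicate 1 alone (90%, exact adjusted p 0.0519) and against CpG-matched genes (65% against 41.9%, permutation adjusted p 0.081). The heme synthesis, progenitor, NK, neuron and pancreas calls also ended under some other promoter definitions or peak lists. Genes are not independent replicates, and each p describes these 2 libraries.

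**Figure D3:**
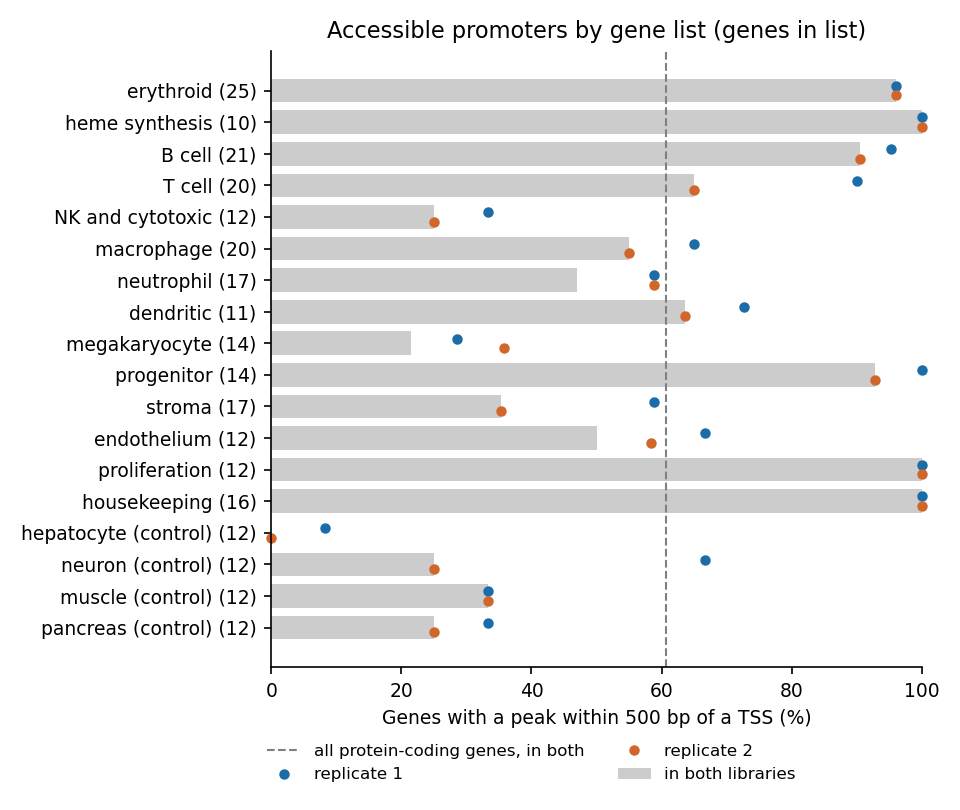
Percent of each list's genes with a peak within 500 bp of a TSS (horizontal axis) in both libraries (bars) and in each (points), for 18 gene lists with their number of genes. Red cell genes reached 96% and B cell genes 90.5%, against 60.7% of all protein-coding genes (dashed line) and 0% of liver genes in both libraries.

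Signal at the strongest promoters of the lists spanned a wide range. In replicate 1 and replicate 2 respectively, Tfrc had signals of 24.1 and 9.04, Epor 17.9 and 6.22, Slc25a38 28.6 and 9.76, and Urod 22.8 and 9.19. Cd22 had 5.71 and 2.34 and Ebf1 5.43 and 2.38. The T cell kinase gene Lck had 14.9 and 5.70, and Lat, an adaptor of the T cell receptor, 1.79 and 0.691. Nr1h3, a sterol-sensing receptor of macrophages, had 7.22 and 6.08, and Slc40a1, the iron exporter, 8.10 and 3.31. The strongest NK promoter was that of Prf1, which encodes perforin (1.26 and 0.423), followed by the cytokine receptor gene Il2rb (0.405 and 0.314). Gfi1, a repressor in granulocyte development, had 2.24 and 0.775, and S100a8, a calcium-binding protein of neutrophils, 1.46 and 0.812. In dendritic cell genes, Bst2 had 9.34 and 4.37 and Zbtb46 7.76 and 4.26. The platelet genes Itga2b, an integrin subunit, and Vwf, von Willebrand factor, had 14.4 and 5.17, and 5.52 and 2.35. The progenitor genes Runx1 and Lmo2 had 6.69 and 2.75, and 4.54 and 2.13. The stroma genes Col1a1, a collagen, and Madcam1, a homing receptor ligand, had 5.68 and 2.86, and 5.58 and 2.32. The vessel genes Egfl7 and Kdr had 1.85 and 0.904, and 1.16 and 0.607. Mcm2, a replication helicase subunit, had 27.0 and 11.5, Ccna2, a cyclin, 25.8 and 11.04, the actin gene Actb 32.9 and 13.2, and the ribosomal gene Rplp0 29.0 and 14.9.

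Some control genes also had a promoter peak in both libraries. In replicate 1 and replicate 2 these included the neuron genes Syn1 (1.73 and 0.599) and Slc17a7 (0.949 and 0.498), the muscle genes Ckm (3.81 and 1.04), Myl2 (3.29 and 1.53) and Tnni3 (1.71 and 1.09), and the pancreas genes Cela1 (4.96 and 4.19), Rbpjl (4.22 and 1.52) and Cpa1 (0.679 and 0.582). The liver gene Apob, a lipoprotein component, had a promoter peak in replicate 1 alone (0.184).

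Red cell and B cell genes had more distal accessible sites around them than random genes. Slc4a1, the anion exchanger of the red cell membrane, had 27 distal sites in both libraries within 50 kb. Pax5, a transcription factor that sets B cell identity, had 13. Red cell genes had a mean of 9.12 distal sites in both libraries, against 4.15 in random lists matched on gene density, at a permutation adjusted p of 0.0036, which rests on the smallest p that 10000 random lists allow (0.0002). B cell genes had 7.14 against 4.13 (permutation adjusted p 0.018). Both means lay above random lists in each library, but neither call held in every library. In replicate 1 alone, red cell genes (13.96 against 8.04, permutation adjusted p 0.054) and B cell genes (13.1 against 8.05, 0.132) were not called, and in replicate 2 alone B cell genes (8.43 against 5.34, 0.0996) were not. The B cell call also ended with a 100 kb window (adjusted p 0.0576), with the stronger part of each list (0.112) and with the shorter deposited lists (0.163), all by permutation. Windows of some red cell genes overlap, those of Hba-a1 (18 sites) with Hba-a2 (17) and of Hbb-bs (15) with Hbb-bt (12). Shared sites were counted more than once, and the random lists were not matched on this. With each site given to its nearest gene alone, and so counted once, the red cell call held.

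**Figure D4:**
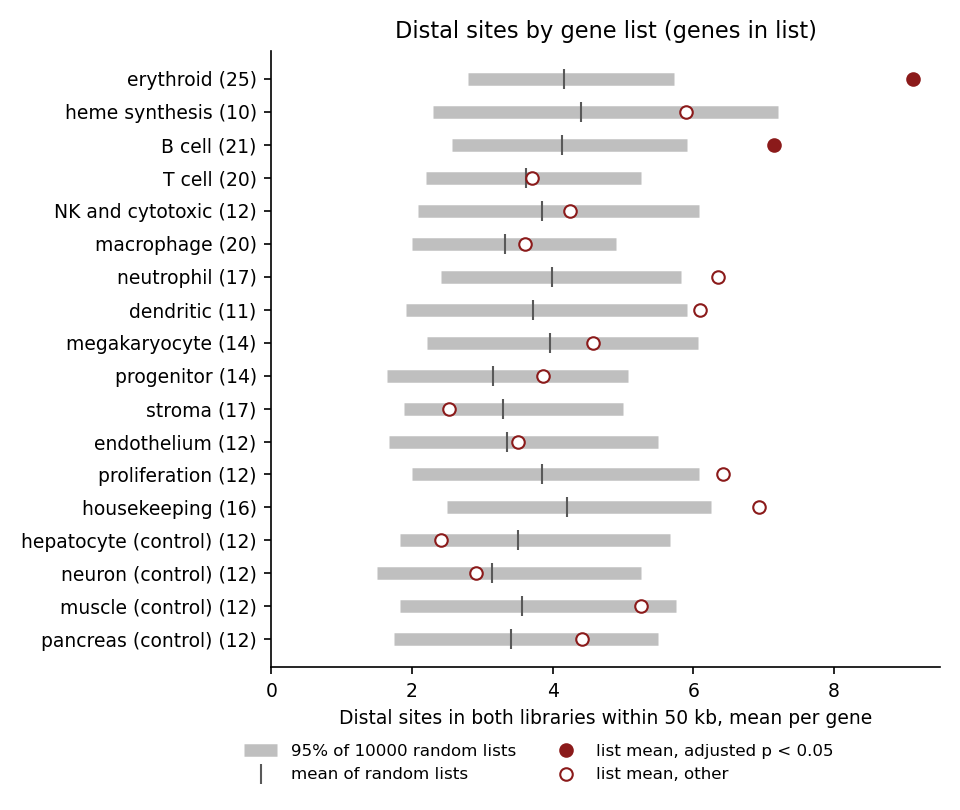
Mean number per gene of distal sites found in both libraries within 50 kb (horizontal axis) for 18 gene lists, against the mean (tick) and the central 95% (band) of 10000 random lists matched on gene density. Filled points passed the adjusted threshold of 0.05: red cell genes at 9.12 and B cell genes at 7.14.

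The other 16 lists were not called by the same permutation test. Housekeeping (6.94 against 4.20) and neutrophil genes (6.35 against 3.99) had an adjusted p of 0.0738 each, proliferation genes (6.42 against 3.85) 0.105, and dendritic cell genes (6.09 against 3.72) 0.129. Under other settings these gained a call by permutation: housekeeping with stronger peaks (adjusted p 0.0216), with nearest genes (0.0192) and unmatched (0.0228), neutrophil unmatched (0.0432), proliferation at 25 kb (0.0456) and dendritic at 100 kb (0.0486). Heme synthesis (5.90), muscle (5.25), megakaryocyte (4.57), pancreas (4.42), NK (4.25), progenitor (3.86), T cell (3.70), macrophage (3.60), endothelium (3.50), neuron (2.92), stroma (2.53) and liver genes (2.42) lay inside the central 95% of their random lists. In their lists, the genes with the most distal sites in both libraries included Aurkb, a mitotic kinase (21), Cel, a pancreatic lipase (15), Mpo, a neutrophil peroxidase (14), and Fech, the last enzyme of heme synthesis (13). Myl2 also had 13, Klrb1c, an NK cell receptor, 12, Neurod2 11, and Ccr7, a homing receptor, and Gp1ba, a platelet adhesion receptor, 10 each. Lmo2 had 9, Hmox1, which breaks down heme, Madcam1 and Pecam1 8 each, the T cell factor Tcf7 7, and liver Ahsg 5.

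Footprints, short protected stretches inside accessible DNA, were more numerous in replicate 1. Replicate 1 had 404781 footprints with a median width of 11 bp, of which 82.2% touched a peak, and replicate 2 had 276537 with a median of 10 bp, of which 86.8% did. Of replicate 1 footprints 40.7% overlapped a replicate 2 footprint, and of replicate 2 footprints 65.3% overlapped a replicate 1 footprint. Inside bases covered by peaks of both, the shares were 59.6% and 75.7%, against means of 40.3% and 48.3% when footprints were placed at random there 100 times. Random placement within the same stretch, chosen after the data were seen, gave 47.4% and 57.4%.

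Footprints in both spleens carried the sequences of CTCF, which anchors chromatin loops, and of blood factors. Among these were the GATA-TAL1 composite and NFE2 sequences of red cell factors, the EBF sequence of the B cell lineage, and the KLF sequence, which includes red cell KLF1. Sequences of widely expressed activators, NRF1, SP and ETS, and of the repressor REST, were enriched as well. The CTCF consensus was 70.4-fold (44.7 to 111) more frequent in replicate 1 footprints than in other positions of the same peaks, and 132-fold (86.2 to 203.5) in replicate 2. NRF1 was enriched 28.0-fold (11.5 to 68.3) and 65.7-fold (21 to 205), EBF 5.74-fold (4.53 to 7.27) and 3.74-fold (2.93 to 4.78), KLF 4.79-fold (4.58 to 5.01) and 3.88-fold (3.69 to 4.07), NFE2 4.02-fold (3.0 to 5.38) and 6.64-fold (4.68 to 9.42), and GATA-TAL1 2.93-fold (2.17 to 3.96) and 3.68-fold (2.52 to 5.37). SP was enriched 10.2-fold and 6.83-fold, ETS 1.89-fold and 1.71-fold, the CAGCTG E-box 1.20-fold and 1.14-fold, and GATA alone 1.11-fold and 1.34-fold. REST, set as a neuronal control, was enriched 78.0-fold (10.9 to 561) in replicate 1, from 1 background count, and at least 35.3-fold in replicate 2, from 0 background counts set to 3. These 11 of 22 sequences passed in both libraries by 2-sided Fisher's exact tests adjusted over 44 tests. The ratios depended on the background. As a geometric mean of both libraries, CTCF went from 96.6 to 5.65, EBF from 4.63 to 2.31 and KLF from 4.31 to 2.17 when the background lay 50 bp to a side of each footprint, where it could overlap other footprints. In that setting NRF1 went from 42.9 to 3.15, REST from 52.5 (replicate 2 at its bound) to 12.7, SP from 8.33 to 2.62, NFE2 from 5.16 to 2.69 and GATA-TAL1 from 3.28 to 2.10. The CTCF mean was 553 without extension of the footprint and 57.3 with 10 bp. The GATA call ended with a 10 bp extension of each footprint and with a background 50 bp to a side.

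The other 11 sequences were not called in both libraries. AP1 (1.18-fold), the PU.1-IRF composite (2.31-fold) and MEF2 (1.91-fold) passed in replicate 2 alone. OCT (0.714), IRF (0.683) and NEUROD (0.715) were below background in replicate 1 alone. PU.1 (0.995 and 1.02), RUNX (0.997 and 1.07), NFY (1.04 and 1.04) and HNF4 (0.969 and 1.30) passed in neither, and HNF1 was too rare for a ratio. Some of these depended on the setting. Without any extension of the footprint, PU.1 (0.466), OCT (0.510) and NFY (0.785) were below background in both libraries. With a 10 bp extension NFY (1.16) and RUNX (1.15) were enriched in both, as was RUNX with the background to a side (1.11). Footprints held 60.2% and 57.1% G and C bases, against 55.0% and 53.5% in their background. In a control chosen after the data were seen, 4 of the 11 enriched sequences (GATA, ETS, EBF and KLF) were also above their consensus read backwards in both libraries. The reversed KLF sequence was itself enriched 3.94-fold and 2.99-fold, and reversed EBF 1.70-fold and 1.89-fold, so a large part of the KLF ratio was shared by a sequence of the same base composition. For CTCF, NFE2, NRF1 and REST the reversed sequence was too rare to compare, for GATA-TAL1 and the E-box the intervals overlapped, and for SP the reversed sequence is the same.

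**Figure D5:**
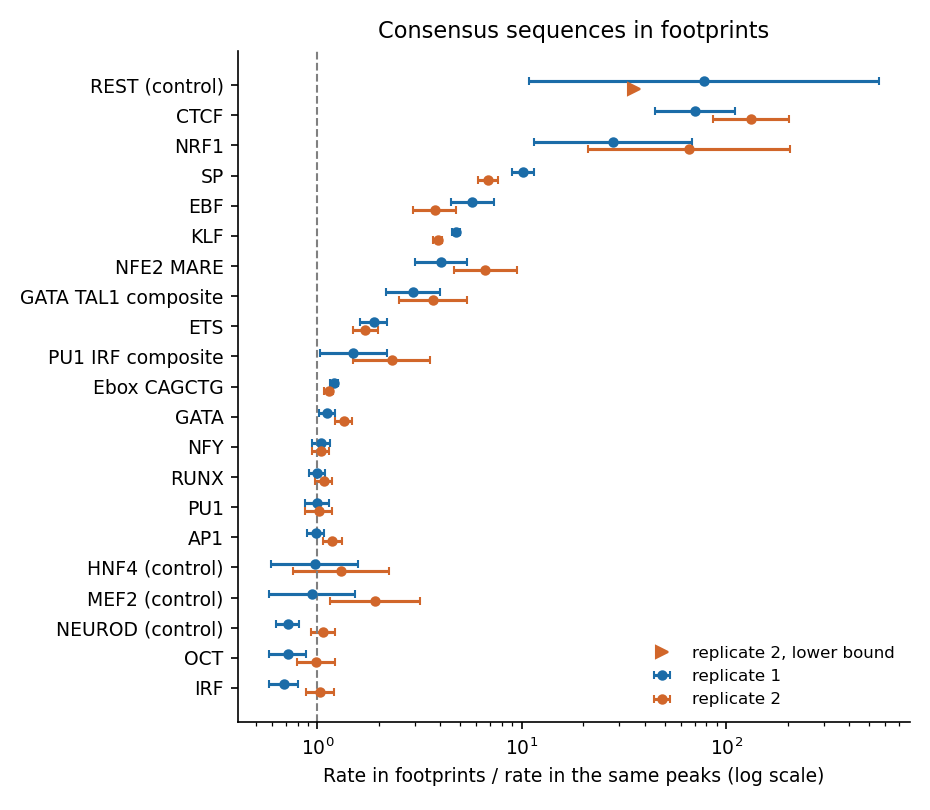
Ratio of the frequency of each consensus in footprints to that in other positions of the same peaks (horizontal axis, log scale), per library with 95% intervals, the triangle being a lower bound. CTCF reached 70.4 in replicate 1 and 132 in replicate 2, and 11 of 22 sequences passed in both libraries.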

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

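The reversed consensus, the random placement within stretches, the variants of the red cell ratio and of its sequence, and the variants of sites called in 1 library were chosen after the data were seen; the other alternatives were not. Of 495 alternatives, 364 kept direction and side of the threshold or stayed within the spread (counts within 1.5 times), 35 lost a call, 26 gained one, 3 reversed and 67 moved; 38 of the last changed sign with no call under either setting. The cause was not tested unless stated. The spread was the SD between the values of the 2 libraries. For shares of peaks and footprints these were the 2 directions of overlap. The spread was thus wide for the full lists, where shares could move far within it, and narrow at matched list length.

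Fewer or stronger features gave lower counts by construction. At a false discovery rate below 0.001, stretches numbered 115771 and 104809. The shorter lists held 83383 and 63374 peaks, and the stronger peaks 65386 and 48116. Footprints without the narrowest and widest numbered 269150 and 176437, and 230133 of replicate 1 lay in peaks of both libraries, of which 60.1% were shared. Requiring reciprocal overlap gave 41.6% of replicate 2 footprints and 64.0% of peaks at matched length, against 79.8% for the shorter lists. Wider or narrower definitions moved the promoter share to 34.8% (1000 bp), 13.5% (100 bp) and 22.7% (protein-coding TSSs), and sites at the 18 loci to 423 (100 kb). Stronger peaks gave a promoter share of 36.2% and an X to autosome density of 0.259, which was 0.379 for the shorter lists.

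Of the alternatives for called promoter lists, 64 of 88 kept the call, for distal lists 10 of 16 and for enriched sequences 53 of 55. Red cell promoters stayed called under each alternative run (80% to 100%), as did B cell promoters (85.7% to 95.2%). Distal sites of red cell genes stayed called in all but replicate 1 alone (4.72 to 15 sites), while B cell genes lost their call in 5 of 8. The shares of peaks found in the other library ranged from 48.9% to 68.6% for replicate 1 and from 66.7% to 92.5% for replicate 2.

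Lists with more open promoters fell from 6 to 2 and lists with fewer from 5 to 0 when matched on promoter CpG. T cell promoters reversed with stronger peaks (25%). Lists with more distal sites went from 2 to 4 without matching on gene density, 1 with the shorter lists, and 0 to 1 when a replicate was left out. Depleted sequences in footprints went from 0 to 3 without extension, which shortens the searched interval, and 0 to 3 when a replicate was left out. PU.1 (0.466) and NFY (0.785) reversed without extension. Enriched sequences fell from 11 to 4 when they also had to exceed their reversed consensus. For CTCF, NFE2, NRF1, REST and SP, among those dropped, that comparison could not be made. Keeping only the stronger footprints was not run, as their value is constant. Read depth being unknown, its part in the difference between libraries was not measured.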

Other observations

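Tests of signal strength on red cell genes, of sites called in 1 library alone, of the calling limit and of sequence copies were chosen after the results were seen, as were all patterns in this part. The genes and regions named here were chosen after their values were seen. Genes and sites are not independent replicates, and each p in this part describes these 2 libraries, not a spread between animals.

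Near red cell genes, distal sites in both libraries were relatively stronger in replicate 2, although replicate 2 had fewer peaks. Their mean log2 ratio of replicate 1 to replicate 2 differed by -0.40 from random lists matched on signal (permutation adjusted p 0.0036, from the smallest p possible). The ratio lay below the random mean in 20 of 22 genes, which argues against strength alone. After centring on signal and on GC content of whole sites in 5 bins, it differed by -0.35 (permutation adjusted p 0.0036). That argues against GC content at this scale only. Sites with the GC-rich NRF1 (0.33) and SP (0.19) sequences stayed shifted toward replicate 1 after the centring. A finer bias of base composition between the libraries thus stays open. Sites with the GATA-TAL1 composite differed by -0.17 from other distal sites (permutation p 0.0002, the smallest possible). A larger share of red cell precursor nuclei in replicate 2 would give this. So would any other cause of stronger signal at red cell sites there, so the test does not tell these causes apart. A difference in how each spleen was dissected or its nuclei were prepared also stays open and untested, since the libraries were taken as separate animals. The design names no biological difference between the animals, so none was tested.

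The ratio near red cell genes was carried in part, but not alone, by the 4 globin genes. Without them it differed by -0.27 (permutation p 0.0038), against -0.40 with them, and leaving out each gene gave -0.42 to -0.35. Sites with the composite outside the red cell and heme windows differed by -0.17. Among the 18 lists, progenitor (0.28, permutation adjusted p 0.018) and neuron genes (0.36, permutation adjusted p 0.0312) were shifted toward replicate 1 when matched on signal. After centring they were not called, with means of 0.12 against -0.05 and of 0.26 against -0.04 in random lists, so the neuron shift stayed of similar size. Heme synthesis (-0.33), NK (-0.30) and proliferation genes (-0.28) had a permutation adjusted p of 0.0582 each, and B cell genes differed by 0.12 (permutation adjusted p 0.186). Of the other sequences, GATA (-0.19), NFE2 (-0.16) and AP1 (-0.06) were shifted toward replicate 2 and KLF (0.03), SP (0.19), NRF1 (0.33) and REST (0.42) toward replicate 1, each at the smallest permutation p. CTCF (0.02), PU.1 (0.04), OCT (0.05) and ETS (0.07) were shifted toward replicate 1 at a permutation adjusted p of 0.0245 or less. The KLF sequence includes that of red cell KLF1, yet its small shift was toward replicate 1. A large part of its footprint ratio was shared by the reversed sequence, so this shift does not decide on the red cell share.

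Of 36 tests of sites called in 1 library alone, by list and library, 3 were called, and only that of red cell genes in replicate 2 was also called outside runs. Red cell genes had 5.36 sites called in replicate 2 alone within 50 kb, against 1.64 in random lists, led by Hba-a1 and Hba-a2 (17 each, windows that overlap) and Hbb-bs (12). Outside runs they exceeded random lists by 3.81 (permutation adjusted p 0.0072), which any cause of the stronger signal in replicate 2 would give, so it is not separate evidence on the share of red cell nuclei. Heme synthesis genes had 7.20 against 1.81, of which 38 sites lay near Cpox alone, and without Cpox the mean was 3.78 (permutation p 0.056). Outside runs they were not called (permutation adjusted p 0.101). With all sites, both lists had a permutation adjusted p of 0.0036 over 36 tests. Progenitor genes had 10.1 sites called in replicate 1 alone against 3.38 (permutation adjusted p 0.0264), with 36 near Myb and 35 near Hoxa9, and were not called outside runs (permutation adjusted p 0.254).

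Runs of at least 10 sites called in 1 library alone, each within 5 kb of the next, numbered 554 in replicate 1 and 51 in replicate 2. Shuffling the labels of sites 100 times gave at most 213 and 7. Runs held 19.7% of the sites called in replicate 1 alone, with a median signal of 0.158 against 0.33 at the others. Among the runs with the most sites in each library, those over genes included 72 sites at Tcn2 and Pes1 on chromosome 11 and 69 at Atf5, Nup62 and Il4i1 on chromosome 7 in replicate 1. In replicate 2 they included 29 at Trpm8 on chromosome 1 and 28 at Eif2ak1, a heme-regulated kinase gene, on chromosome 5. In replicate 1, 5842 of the 13048 peaks of the lowest signal decile lay in runs (44.8%), against 2350 of the 13048 in the next decile.

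The lowest signal decile of replicate 1 peaks was rarely found in replicate 2. It had the largest repeat-masked share of the replicate 1 deciles (31.5%). Of its 4266 peaks without a repeat-masked base, 2.91% (2.42 to 3.46) were found, against 2.90% of all its peaks. In the next decile, 14.1% (13.2 to 14.9) of peaks without such a base were found. This argues against masked repeats inside the peaks as the cause, for those peaks only. Unmasked sequence can also have copies, as at the Dynlt1b and Lars2 sites, so reads from unmasked copies stay open. Of replicate 2 peaks, 1.24% lay at or below the decile's median signal of 0.124, but signals of the libraries are not on the same scale, so this does not measure the calling limit of replicate 2, which stays open.

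Several of the highest signals lay in repeats or gene copies. Of the 5 strongest distal sites, 3 had another copy of at least 95% identity over at least 50% of their length elsewhere in the reference, against 10 of 200 random distal sites (5%), and so did 4 of the 5 strongest sites overall. The sites at Cers5, near Ell and at Fzr1 had 0 other copies. Whether reads shared between near-identical copies raised these signals stays open, since the copies were counted on the sites that prompted the question.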
